A study of Mus musculus with 96 samples.

How the data were processed

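The series held 96 single-cell RNA-seq libraries, each made from 1 mouse spleen cell, and each GEO sample was 1 cell. The cells came from 2 moribund mice with acute myeloid leukemia, 48 cells from each, both of the genotype Flt3ITD/ITD;Dnmt3afl/- with MxCre. Per the labels' protocols, splenocytes were enriched for c-Kit (CD117) with magnetic beads, captured on a Fluidigm C1 chip in 2 independent rounds of 52 and 56 cells, and converted to cDNA with the SMARTer kit. Libraries of the first 48 visually scored single cells of each round were made from 125 pg of cDNA with Nextera XT, pooled and sequenced together on an Illumina HiSeq instrument. Splenocytes of the control genotype named in the protocols were not analysed here.

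Expression came from a pair of deposited tables. The main table held TPM values, abundance scaled to a fixed total per cell, which the authors made with RSEM per the file's name, for 23955 gene symbols, and every cell's TPM values summed to 1000000. The other table held RPKM values, reads scaled by gene length and library, deposited by the authors under the name of AltAnalyze, for 9310 Ensembl gene identifiers. Per the submitters' processing notes, TopHat2, RSEM and Bowtie2 were used and the genome builds were mm10 and mm9; which build belonged to which table, and the versions, were not given in the sources used here. Of the RPKM values, 89.6% lay at a floor of their gene, a value shared by many cells, and 34 genes had no such floor. Low values above the floor were whole multiples of what 1 read was worth, within 0.1 of a read, for 100% of the values looked at. TPM keeps no read depth, and reads recovered from the RPKM table were not used as depth, because RPKM values lay far below TPM for most genes but not for genes of some regions. Total sequencing depth was therefore unknown, and the number of genes at 1 TPM or more stood in its place. Recovered reads, a partial count, had a median per cell of 362500 in mouse 1 and 292653 in mouse 2. Their range over both mice was 73986 to 644877. A total of 8236 genes were matched between the tables by symbol, and 0 columns of either table were left without a sample.

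Cells of 1 animal are not replicates, so each side of the comparison had 1 animal. No test, p-value, standard error or count of changed genes was made from cells. Column names in the TPM table carried a prefix that divided the cells exactly as the mice did, and 0 libraries of mouse 2 had the prefix of mouse 1, so mouse cannot be told apart from capture round, and the sexes of the mice differed as well. Both mice had the same genotype, so no value below is an effect of Dnmt3a or Flt3. A gene-level value of Dnmt3a does not separate the floxed exons from the rest of the gene and does not check the deletion.

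Values were taken as log2(TPM + 1), and differences on this scale understate the change of low genes. In the simulated data below, they also understated that of genes with a mean of 10 TPM or more. Mouse differences were mouse 2 minus mouse 1 of the mean over cells. Before the data were examined, 29 gene lists with 386 genes were fixed, of which 376 were in the TPM table, together with the markers of 12 cell types. A list was described when 3 or more members had a mean of 1 TPM or more, which 27 lists did; the B cell and mitochondrially encoded lists did not. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 50 bins. These percentiles describe these libraries and are not p-values. Shares of cells carry exact (Clopper-Pearson) 95% intervals, which cover the counting of cells only; the share of 0 for Xist was given the limit that 3 counts allow, and the closing section uses upper exact bounds for shares of 0.

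Variable genes were those with a high standard deviation of log2(TPM + 1) over the cells of 1 mouse relative to genes of like mean (20 bins), among genes at 1 TPM or more in at least 5 cells of each mouse; the top 10% of both mice were compared. Co-expression within a list was the mean pairwise Spearman correlation over the cells of 1 mouse after a linear fit on the number of detected genes, placed among 1000 random lists. For clusters, the 500 most variable genes that were in no fixed list were freed of mouse and detected-gene number by a linear fit, reduced to 10 principal components and clustered with Ward's method; the number of clusters, from 2 to 6, was the one with the highest mean silhouette width. No doublet caller was run, because the chambers were scored by eye per the labels' protocols and 96 cells are few.

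Genes were named by a rule fixed before the data were examined. It took Kit, Flt3, Dnmt3a and the sex-linked genes; up to 12 genes per mouse with a difference of at least 1 in both tables, detected in at least 24 cells of the mouse where they were higher and with a mean of 10 TPM there, leaving out Gm and Rik names; the most abundant and most different members of each list; the 15 most variable genes; the 10 leading genes of each cluster; and the more frequent lineage markers. Genes named outside it are said to be. Some genes that the rule takes are not reported here.

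Settings fixed for variation before the data were examined were the pseudocount, the detection threshold, the filter on low values, the scaling, the table, the removal of detected-gene number, the number of genes and components, and the clustering method. Alternatives chosen after the data were seen were detection at 10, 100 and 1000 TPM, lists and co-expression without the dendritic cell-like cluster, lists and correlations between lists without the neutrophil gene-led cluster, and a division into 4 clusters. Coordinates are from GENCODE M21 (GRCm38, the assembly also named mm10). For the ratio of the tables, RPKM values at the floor were taken as 0 and 0.01 was added to the mean RPKM of a gene.

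The steps were tested on simulated data made from the cells of mouse 1, divided at random into 2 sides, with 10688 genes. Of these, 200 with a mean of 10 TPM or more were changed by 2 on the log2 scale on 1 side. The sign was right for 86.0% of the changed genes, and the median difference recovered was 0.77 for raised and -0.61 for lowered genes. Of 200 unchanged lists of 12 genes, 7.5% fell outside the central 95% of random lists, more than the nominal share, and a list of changed genes lay at percentile 99.9. Members of the unchanged lists were drawn at random, unlike fixed lists whose members vary together. How often a co-expressed list falls outside the random range was therefore not tested. A planted group of 20 cells was recovered with an adjusted Rand index of 1. These cells were drawn at random, so the recovery of a group with fewer detected genes was not tested. Of the 60 genes planted to vary, 25 were in the top 10% of both sides. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.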

Results

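Single-cell RNA-seq was carried out on 96 c-Kit-selected splenocytes from 2 mice with acute myeloid leukemia, 48 cells from each. The series addresses the expression changes that go with loss of Dnmt3a function in leukemia driven by an internal tandem duplication of Flt3, a receptor tyrosine kinase of blood progenitors. Dnmt3a is a DNA methyltransferase, and c-Kit, the receptor of stem cell factor, marks stem and progenitor cells. Both mice had the same genotype, so the comparisons here are between the leukemias and among their cells. A median of 3606 genes per cell (range 1759 to 5559) reached 1 TPM in mouse 1 and 3083 (1604 to 6018) in mouse 2. The 10 most abundant genes of a cell held a median of 9.61% of its TPM in mouse 1 and 22.99% in mouse 2. There is 1 animal per side and no replicate check of any difference between the mice.

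Kit, the gene of the selected receptor (chromosome 5, 75574916 to 75656722, GRCm38), was detected at 1 TPM or more in 40 of 48 cells of mouse 1 (83.3%, exact 95% interval 69.8 to 92.5) and in 31 of 48 cells of mouse 2 (64.6%, 49.5 to 77.8). Its mean was 145 and 82.5 TPM. At 10 TPM, a threshold added after the data were seen, the shares were 68.8% and 45.8%. Flt3 (chromosome 5, 147330741 to 147400489) was detected in 22 and 21 cells, at a mean of 51.9 and 92.5 TPM. Dnmt3a (chromosome 12, 3806007 to 3914443) was detected in 19 and 17 cells, at 18.8 and 22.1 TPM. All 3 are protein-coding genes, and the values are for the whole gene. Xist, the noncoding RNA of X inactivation (chromosome X, 103460366 to 103483254), was detected in 45 cells of mouse 1 and 0 of 48 of mouse 2, which allows a share of up to 6.25%. The Y-linked genes Ddx3y and Eif2s3y were detected in 0 cells of mouse 1 and in 33 and 23 cells of mouse 2, Uty in 0 and 9, and Kdm5d in 0 and 7.

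**Figure D1:**
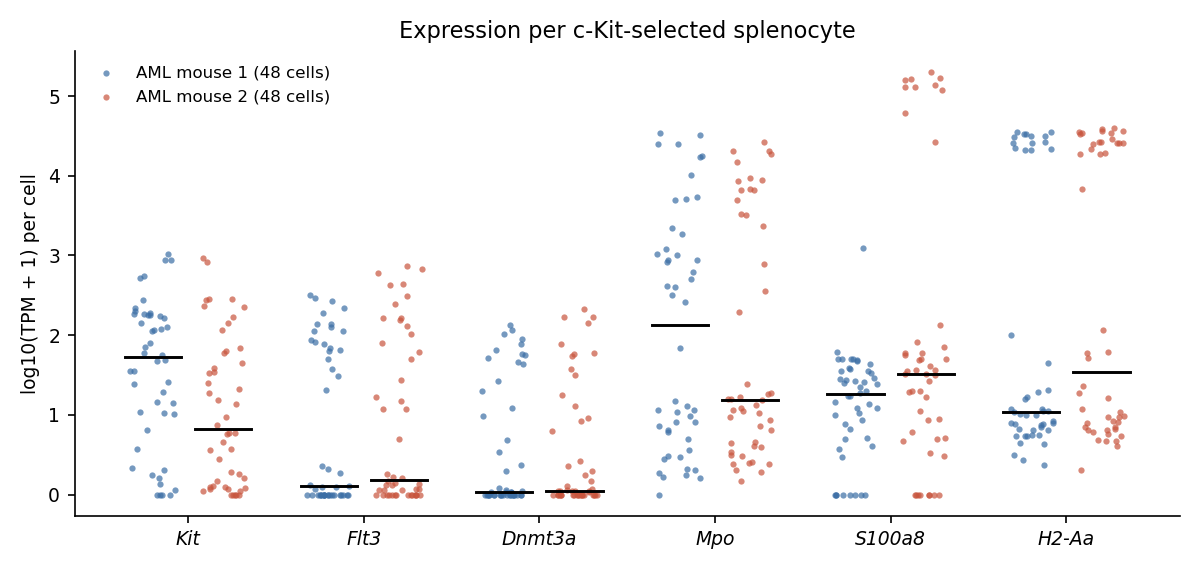
Each point is 1 cell (48 per mouse), the vertical axis is log10(TPM + 1), and the black bar is the median. H2-Aa divides the cells of both mice into groups far apart, with 14 cells of mouse 1 and 20 of mouse 2 at 1000 TPM or more, whereas S100a8 does so in mouse 2 with 10 cells against 1 in mouse 1.

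The comparison of the mice asked how alike leukemias of the same genotype were. The list that differed most was late neutrophil, genes of granule and S100 proteins made late in granulocyte maturation, with a median difference of 1.95 on the log2 scale and 12 of 13 measured members higher in mouse 2. S100a8 (chromosome 3, 90668978 to 90670035) had a mean of 45.6 TPM in mouse 1 and 27037 TPM in mouse 2, S100a9 13.7 and 21070, Ngp 13.2 and 18073, and Camp, the cathelicidin precursor, 12.98 and 8238. The dendritic cell list was 1.04 higher (8 of 10 members), a value that was 0.13 with detected-gene number removed and turned to -0.17 in the RPKM table, with Cd74, the class II invariant chain, at 7170 and 12267 TPM and Clec9a at 41.2 and 170 TPM. The monocyte and macrophage list was 0.80 higher (10 of 12), with lysozyme gene Lyz2 at 499 and 3765 TPM and Ly6c2 at 573 and 1638. The granulocyte-monocyte progenitor list was 0.58 higher, with 8 of 14 members higher: Clec12a had 211 and 356 TPM and Igsf6 47.5 and 177, whereas Ctsg, coding for cathepsin G, had 694 and 453 and Mpo, the myeloperoxidase gene, 3946 and 3403. The interferon response list was 0.40 higher (14 of 16), with Mx1 at 2.997 and 82.5 TPM. All 5 lists lay at percentile 100 of the random lists.

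The lists lower in mouse 2 beyond the random range were those of T and NK cells and of mast cells and basophils. The T and NK cell list differed by -0.37 (7 of 9 members lower, percentile 0.93; -1.29 over the 3 members with a mean of 10 TPM or more), with Nkg7 at 1530 and 841 TPM, and the mast cell and basophil list by -0.73 (3 of 4 lower, percentile 2.07), with Cpa3 at 305 and 134 TPM. The erythroid (-0.31, 9 of 9 lower) and megakaryocyte lists (-0.25, 8 of 8 lower) lay just inside the random range, at percentiles 3.69 and 3.64. The erythroid list includes the globin genes Hbb-b2 and Hbb-bt, whose values were identical and are uncertain because these are near-identical copies, so 9 of 9 may count 1 measurement under both names. The stem and early progenitor list differed by -0.29 with 10 of 13 members lower (Cd34 384 and 188 TPM, Angpt1 120 and 25.97), and the Hox and Meis list by -0.24 (Meis1 155 and 64.5 TPM); both were inside the random range. So were STAT5 and MAPK feedback targets (-0.39; Socs2 315 and 168 TPM), DNA methylation machinery (-0.29), S phase (-0.35), G2 and M phase (-0.09), glycolysis (-0.48), oxidative phosphorylation (-0.78), cytosolic ribosome (-0.75), housekeeping (-0.63), apoptosis and p53 (-0.47), immediate early and heat shock (-0.48; Fos 404 and 134 TPM), myeloid transcription factors (-0.69; Gfi1b 173 and 4.62 TPM), surface receptors (-0.28), eosinophil (0.21) and stromal and endothelial genes (-0.26).

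**Figure D2:**
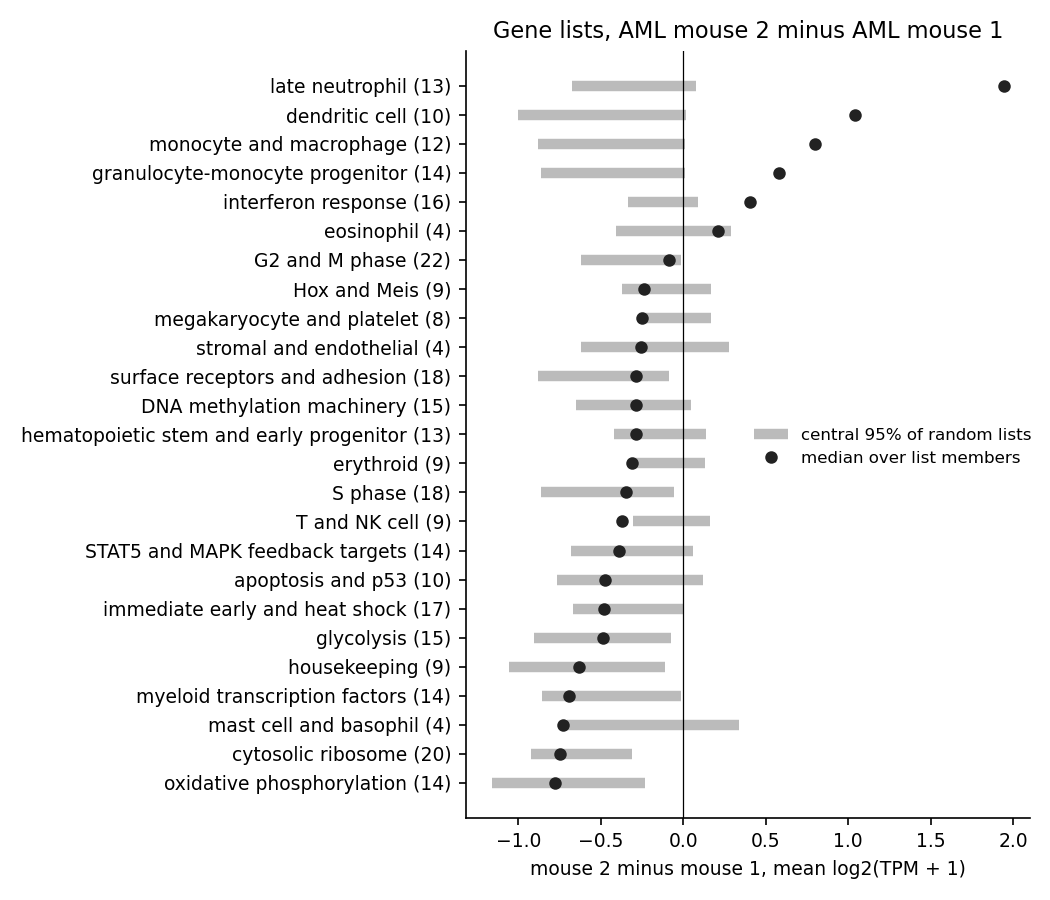
Points give each list's median difference of mean log2(TPM + 1), mouse 2 minus mouse 1, with the number of members in brackets, and grey bars the central 95% of 10000 random lists. The late neutrophil list stands farthest out at 1.95, and most other lists lie inside their bars, which are centred below 0.

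Several of these differences rested on groups of cells. Without the cluster led by neutrophil genes, chosen after the data were seen, the late neutrophil difference was 0.27 that of the granulocyte-monocyte progenitor list -0.15 and that of the dendritic list 1.95. This cluster held 8 cells of mouse 2 and 1 of mouse 1. The latter had its leading genes below the mean of those 8 cells (S100a8 41.9 against 133623 TPM, Camp 6.13 against 48804). Against the mean of the other cells of mouse 1, some leading genes were lower in it (S100a8 45.7 and Camp 13.1 in the others). Others were higher, such as Cybb (173 against 9.88) and Ngp (20.1 against 13.1). Without the dendritic cell-like cells, the dendritic list differed by -0.08 and the late neutrophil list by 3.33. Across 11015 genes, the mouse means had a Pearson correlation of 0.953 and a Spearman correlation of 0.901, and genes are not independent replicates. The median difference was -0.20 over these genes and -0.54 over the 2051 genes detected in at least 24 cells of both mice. Centring on the latter adds the same amount to every gene, so lists between -0.54 and 0 change sign, and no list changes its place among random lists.

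The rule on single genes took 12 genes higher in mouse 1 and the 10 that were eligible in mouse 2. In mouse 1 these were Serpina3g, a serine protease inhibitor (768 TPM against 361, difference -3.21), Car2, coding for carbonic anhydrase 2 (559 against 135, -3.20), Muc13 (383 against 167, -2.86), Ptprcap (232 against 104, -2.80), Bex6 (212 against 50.4, -2.79), Ndufv1 (146 against 28.7, -2.61), Ifitm1 (3407 against 2449, -2.43), Rsl1d1, Uba2, Rela, Klhl6 and Pdia6. In mouse 2 they were S100a9 (2.69), Ngp (2.64), S100a8 (2.63), Ly6c2 (2.56), Camp (2.35), Ltf, the lactoferrin gene (1.95), Cdk2ap2 (1.57), Mctp1 (1.45), Sdf2l1 (1.21) and Unc93b1 (1.10). In the mouse where the gene was higher, the standard deviation over cells exceeded the difference for every one of these genes (4.49 for Serpina3g in mouse 1); in the other mouse it was smaller than the difference for several, such as Ltf (1.01 in mouse 1). Because the rule needed both tables, it favoured genes in regions where RPKM values were not far below TPM: 9 of the 12 and 3 of the 10 lay there. On TPM alone, a rule chosen after the values were seen, mouse 1 also had Erich1 (61.6 against 9.15 TPM), Pdlim1 and Rgs18, and mouse 2 Dstn (134 against 621 TPM), Apobec3 (29.8 against 197 TPM) and Dnase1l3 (187 against 2911 TPM).

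Markers of several lineages were found in the selected cells. Because low values of Ngp followed the cell numbering, shares are given at 100 TPM, a threshold added after the data were seen. Ifitm1, the most frequent stem and early progenitor marker, was at this level in 31 of 48 cells of mouse 1 (64.6%, 49.5 to 77.8) and 20 of mouse 2 (41.7%, 27.6 to 56.8). Clec12a of the granulocyte-monocyte list was so in 21 and 27 cells, Lyz2 in 32 and 29, and H2-Ab1, a class II chain, in 18 and 24. S100a8 reached it in 1 cell of mouse 1 (2.08%, 0.0527 to 11.1) and 11 of mouse 2 (22.9%, 12.03 to 37.3). Nkg7 was at 100 TPM in 33 and 21 cells, Hbb-b2 in 18 and 5, Mcpt8, a basophil protease gene, in 13 and 6, Cd79b of the B cell list in 10 and 6, Pecam1 in 10 and 1, Ear2 in 5 and 7, and Gp9 in 2 and 1. Each of these is the most frequent member of its list and does not by itself show that lineage. Few members were at 1 TPM or more in at least 5 cells of each mouse: 1 of 12 in the B cell list, 3 of 14 in T and NK cell, 2 of 10 in stromal and endothelial and 1 of 9 in eosinophil. The same held for 1 of 10 in megakaryocyte and platelet and 2 of 10 in mast cell and basophil. In the erythroid list it held for 3 of 15, among them Hbb-b2 and Hbb-bt with identical values. At 1000 TPM, Mpo was found in 14 and 15 cells and Elane, coding for neutrophil elastase, in 7 and 11. At the planned threshold of 1 TPM, H2-Aa and H2-Ab1 were detected in 48 of 48 cells of both mice.

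The low level of Ngp followed the cell numbering. It was below 1000 TPM in every cell of mouse 1, yet at positions of the numbering by 8 that also held a cell at 1000 TPM or more its median in mouse 1 was 14.6 TPM (36 cells), against 0.56 TPM (12 cells) at positions that held none. In mouse 2 the corresponding medians below 1000 TPM were 18.9 (26 cells) and 0 TPM (12 cells). Xist had a mean in mouse 2 of 0.0796% of its mean in mouse 1, with 25 of 48 cells above 0. Ddx3y and Eif2s3y had means in mouse 1 of 0.0465% and 0.0362% of those in mouse 2, with 5 and 4 of 48 cells above 0.

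**Figure D3:**
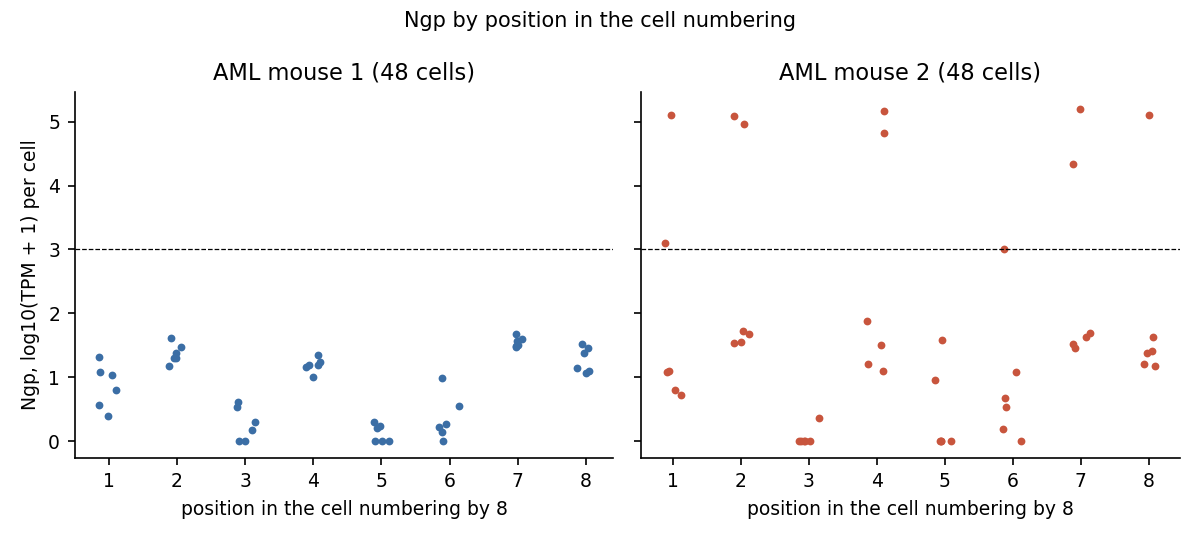
Each point is 1 cell, placed by its position in the cell numbering by 8 (horizontal) and its Ngp level as log10(TPM + 1) (vertical), with a dashed line at 1000 TPM. In mouse 1 the cells at positions 3 and 5, where no cell of either mouse reaches the line, lie lowest, together with those of position 6.

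Clustering gave 2 clusters (mean silhouette width 0.201). Cluster 1 was led by Cd74, H2-Aa, H2-Eb1 and H2-Ab1, genes of class II antigen presentation, with Ifi205, Ctss, Cd36, Naaa, Dnase1l3 and 5430435G22Rik, and is called dendritic cell-like. It held 10 of 48 cells of mouse 1 (20.8%, 10.5 to 34.99) and 12 of mouse 2 (25%, 13.6 to 39.6). For 1 of the 12 the name does not hold, since it had H2-Aa at 8.39 TPM, Mpo at 8950 TPM and 6018 detected genes. That cell enters every contrast of cluster 1 in mouse 2. Cluster 2, left unnamed, was led by Plac8, Cd63, Lgals9, Stmn1, Lbr, Serpinb1a, Ifitm2, Fam107b, Gstm1 and Ncoa4. The fixed lists did not enter the clustering. Removing detected-gene number divided the class II-high cells: H2-Aa (chromosome 17, 34282744 to 34287823) was at 1000 TPM or more in 14 cells of mouse 1 (29.2%, 16.95 to 44.1) and 20 of mouse 2 (41.7%, 27.6 to 56.8), of which 10 and 11 were in cluster 1 and 4 and 9 in cluster 2. With mouse alone removed, a setting chosen before the data were examined, the dendritic cell-like cluster had 14 and 21 cells. These cells had fewer detected genes than the others, with medians of 2921.5 against 3980.5 in mouse 1 and 2526 against 3888 in mouse 2.

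Dendritic cell-like cells, which also had fewer detected genes, had lower S phase and progenitor genes in both mice. In cluster 1 the dendritic list was 6.87 and 5.32 higher than in cluster 2 (mouse 1 and mouse 2), the S phase list differed by -2.49 and -1.28 (17 of 18 members lower in both, percentiles 0.01 and 0.06), granulocyte-monocyte progenitor by -1.70 and -2.47 (13 of 14), stem and early progenitor by -0.96 and -0.54 (12 of 13) and STAT5 and MAPK feedback targets by -1.31 and -0.79 (10 of 14). The monocyte and macrophage list was 0.53 and 0.48 higher in cluster 1 (7 of 12 members higher in both, percentiles 99.4 and 97.3). With mouse alone removed that list differed by 0.41 and -0.405. G2 and M phase differed by -1.04 and -1.10 (18 of 22), which was inside the random range in mouse 1 (percentile 13.2) and at percentile 0 in mouse 2. With mouse alone removed, the S phase difference was -2.90 and -3.38 (18 of 18) and that of G2 and M phase -1.35 and -2.61 (22 of 22), without a placement among random lists. Lower values were not particular to these lists: oxidative phosphorylation differed by -1.44 and -1.82 (12 of 14 lower in both) and housekeeping by -0.94 and -0.97. The cytosolic ribosome list differed by -0.68 and 0.05. In that grouping Xcr1, a chemokine receptor of cross-presenting dendritic cells, was at 10 TPM or more in 14 of 14 and 21 of 21 dendritic cell-like cells and in 0 of 34 and 0 of 27 others. Clec9a was so in 11 of 14 and 17 of 21 (0 of 34 and 2 of 27 others), and Batf3, a transcription factor of the same lineage, in 11 of 14 and 17 of 21 (0 of 34 and 1 of 27 others). Itgax was less frequent (8 of 14 and 8 of 21), and so were Zbtb46 (3 of 14 and 2 of 21) and Cd8a (2 of 14 and 0 of 21), the former outside the naming rule and chosen after its values were seen. Siglech, a plasmacytoid marker outside the naming rule and chosen after its values were seen, was so in 0 of 14 and 0 of 21. Mean Flt3 was 93.1 TPM in these cells against 34.95 in the others of mouse 1, and 182 against 22.9 in mouse 2. Kit reached 10 TPM in 8 of 14 and 10 of 21 of them, and in 25 of 34 and 12 of 27 of the others.

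**Figure D4:**
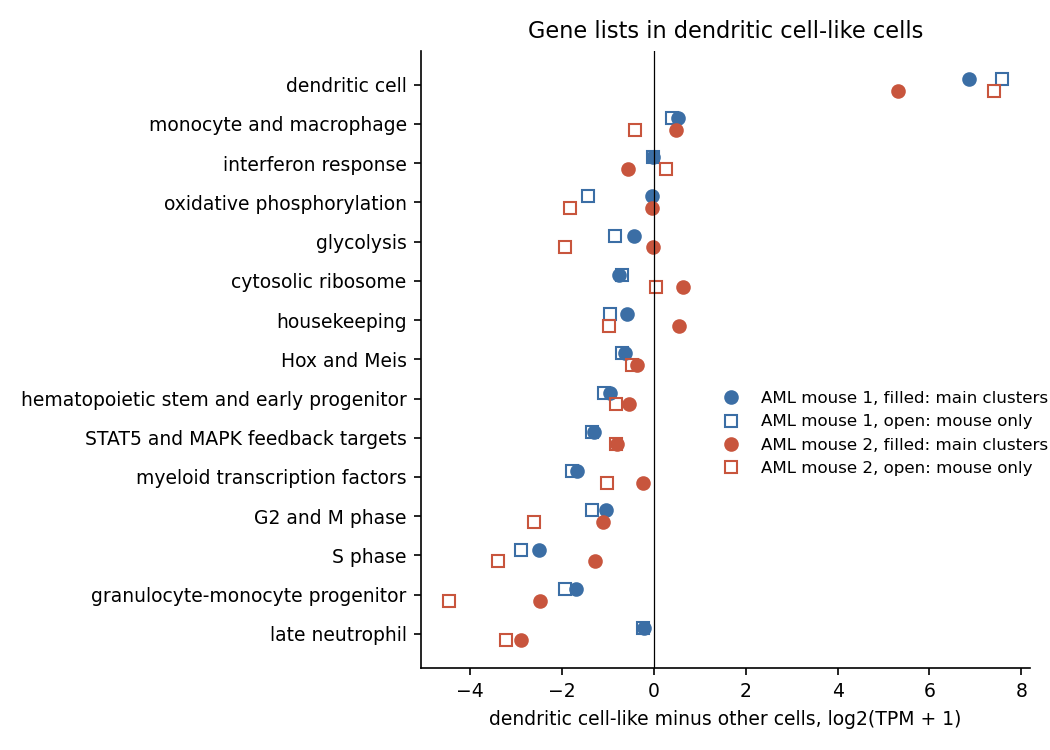
Points give each list's median difference in log2(TPM + 1), dendritic cell-like minus other cells, in each mouse; filled circles are the clusters with mouse and detected-gene number removed and open squares those with mouse alone removed. The dendritic list lies between 5.32 and 7.58, and the S phase and progenitor lists lie below 0 in both mice and both groupings.

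The genes that varied most among cells overlapped between the mice more than independent lists would. Of 8008 genes, 801 formed the top 10% of each mouse and 325 were in both, against 80.1 for independent lists (4.06 times), and the standardized spread had a Spearman correlation of 0.696 across genes. Among the 15 highest were H2-Aa, Cd74, H2-Eb1, Plbd1, Naaa, Mpo, Bcl2a1d, Ctss, Bcl2a1a, H2-Ab1, Id2, Ctsg, Treml4 and Tnfrsf18. Bcl2a1a and Bcl2a1d are near-identical copies and uncertain. The shared set held 7 of 9 dendritic, 7 of 12 granulocyte-monocyte progenitor (among them Mpo, Ctsg, Elane and Prtn3) and 5 of 10 monocyte genes, 2 of 22 G2 and M phase genes, 0 of 8 late neutrophil and 0 of 20 ribosomal genes.

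Members of several lists varied together within each mouse. The mean correlation between members was 0.55 in mouse 1 and 0.62 in mouse 2 for G2 and M phase, 0.49 and 0.59 for dendritic cell, 0.32 and 0.40 for granulocyte-monocyte progenitor, 0.25 and 0.19 for S phase, 0.20 and 0.29 for stem and early progenitor and 0.29 and 0.55 for cytosolic ribosome genes, each at percentile 100. The late neutrophil list had 0.65 and 0.67, and in mouse 1 all but 1 of its cells lay below 1000 TPM for these genes, at low levels that followed the numbering in the case of Ngp. DNA methylation machinery had -0.03 and 0.05. Without the dendritic cell-like cells, the correlation of the dendritic list was 0.06 and 0.17 and that of the stem and early progenitor list 0.06 and 0.16.

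The deposited tables differed. Over 8236 shared genes the Spearman correlation of TPM and RPKM within a cell had a median of 0.379 (range 0.169 to 0.458), and it was -0.21 over genes at 1 or more in both. Each of the 96 cells had its own RPKM column as the best match among all columns. Of 1258 genes with a mouse difference of at least 1 in TPM and any difference in RPKM, 1014 (80.6%) had the same sign in RPKM. Among 5825 genes with a mean of 10 TPM, RPKM exceeded TPM by a median of 2.11 on the log2 scale for 414 genes that lay before 1 split point per chromosome, and the difference was -8.03 for the 5411 after it. The correlation of the tables within a cell had a median of 0.785 over genes before the split and 0.420 over those after it. On chromosome 16, 196 of 215 genes had a ratio above -3, and on chromosome 19 the region ended near 6399340. A single split did not describe every chromosome: chromosomes 4 and 6 had 28 of 339 and 37 of 309 genes above -3, but 0 genes before a split. Kit was above its RPKM floor in 12.5% and 4.17% of cells, far below its share in TPM.

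**Figure D5:**
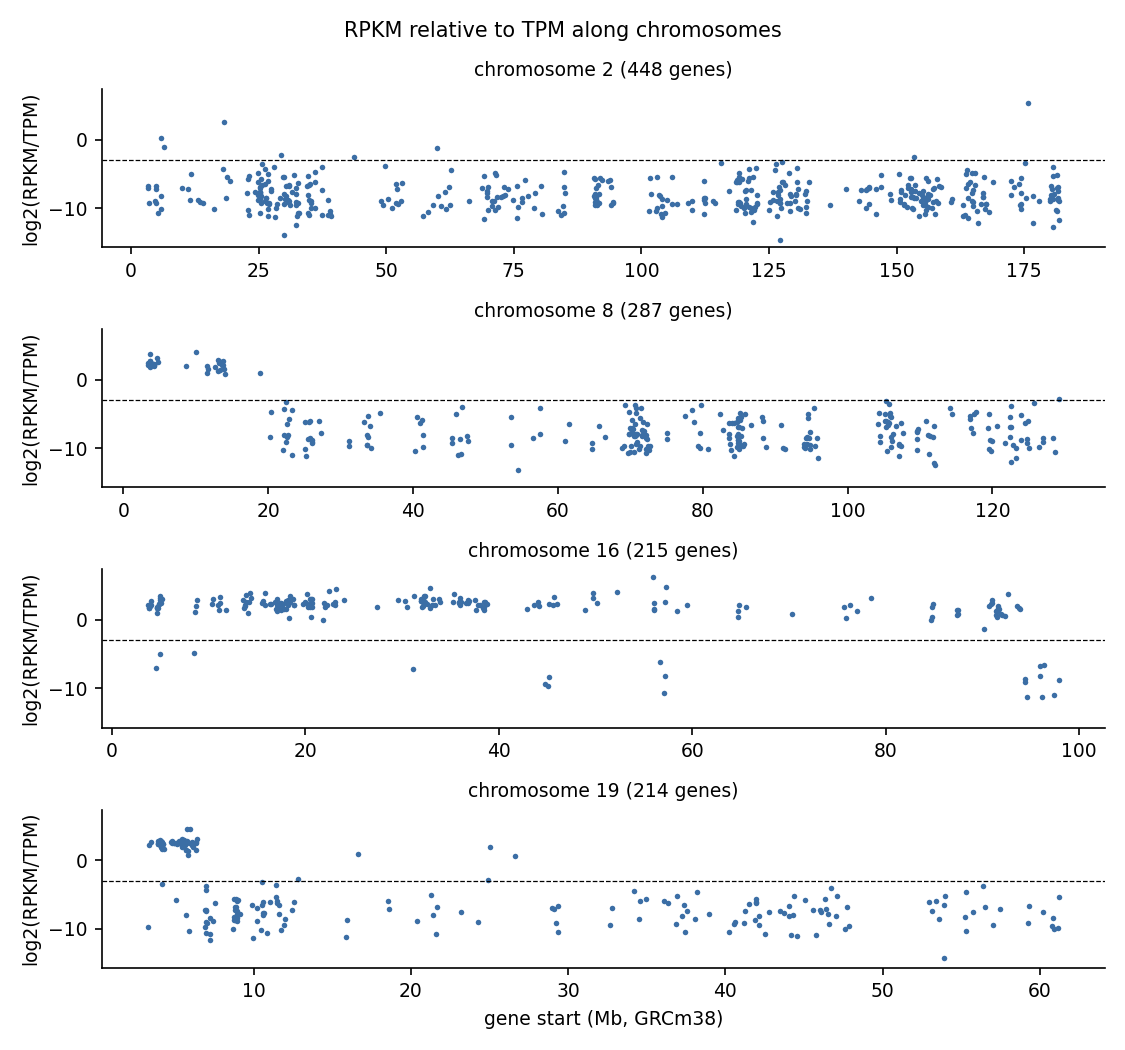
Each point is a gene, placed by its start in Mb (GRCm38) and its log2 ratio of mean RPKM to mean TPM on chromosomes 2, 8, 16 and 19, with a dashed line at -3. High ratios fill most of chromosome 16 and the beginning of chromosomes 8 and 19, and are few on chromosome 2 (8 of 448 genes).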

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

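No test was run in this part, and each difference between the mice below was not tested, since each side is 1 animal. Contrasts of cluster 1 (dendritic cell-like) minus cluster 2 were searched for opposite directions in the mice, by at least 0.5 on the log2 scale in each, over the lists and, taken singly, Kit, Flt3 and Dnmt3a. Other single genes were left out of the search, and some of them, such as Cd209a (-0.69 and 0.54, named after its values were seen), have contrasts of that kind. Dnmt3a differed by -2.06 in mouse 1 and 1.83 in mouse 2, a gap of 3.89. The cytosolic ribosome list differed by -0.75 and 0.63, a gap of 1.38, and the housekeeping list by -0.59 and 0.54, a gap of 1.13. The list made of Kit, Flt3 and Dnmt3a also met this, with -0.86 and 1.83, but its median is the value of a single member, Kit in mouse 1 and Dnmt3a in mouse 2. In the planned grouping with mouse alone removed, Dnmt3a differed by -1.11 and 1.17, the ribosome list by -0.68 and 0.05, and the housekeeping list by -0.94 and -0.97, so that the ribosome and housekeeping lists did not keep opposite signs of that size; the list of Kit, Flt3 and Dnmt3a did only through Dnmt3a, whose values were its medians. Dnmt3a was at 10 TPM or more in 2 of 14 dendritic cell-like and 12 of 34 other cells of mouse 1, and in 8 of 21 and 4 of 27 of mouse 2.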

How the results depend on the processing

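Alternatives at 10, 100 and 1000 TPM, without the dendritic cell-like or neutrophil gene-led cells, and at 4 clusters were chosen only after the result was seen; the others were planned. The planned filter on cells low in detected genes removed 0 cells and moved nothing. Of the other 1253 values under alternatives, 1031 stayed within the spread given to them. That count did not require the same sign for lists inside the random range, so it includes changes of sign. It also includes values that could not move. For single genes, the setting without a filter repeated the main value. At the next number of clusters and at 4 clusters, the dendritic cell-like cluster kept its 10 and 12 cells. Its shares and contrasts there repeated the main ones. Of the 159 among the 1253 that belong to a result answering a comparison, 112 stayed within their spread and 5 reversed, 1 of these by centring alone. Every RPKM value is limited by that table's low values for most genes, and a gene counted as detected there when it was above its floor. Except where the setting itself removes cells or genes, the cause was not tested.

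Shares of cells. In RPKM, Kit was in 12.5% and 4.17% of cells (mouse 1 and mouse 2) and Flt3 in 10.4% and 16.7%. At 10 TPM Kit was in 68.8% and 45.8%. Above 0, Kit was in 89.6% of mouse 2 cells, Flt3 in 70.8% of mouse 2 cells, and Dnmt3a in 56.3% and 60.4%. The dendritic cell-like share was 39.6% and 47.9% with k-means, 35.4% and 47.9% with 5 components, 41.7% and 43.8% in RPKM, and in mouse 2 43.8% with mouse alone removed and with neither removed. The number of clusters was 6 with 1000 genes and 4 in RPKM.

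Mouse 2 minus mouse 1. With the log2 ratio of mean TPM the correlation of mouse means was 0.804. Without the neutrophil gene-led cells the granulocyte-monocyte progenitor list reversed to -0.15, the late neutrophil list fell to 0.27 and the dendritic list went to 1.95. Without the dendritic cell-like cells the late neutrophil list was 3.33 and the dendritic list reversed to -0.076. The dendritic list was 0.13 with detected-gene number removed and reversed to -0.17 in RPKM. Centring adds 0.54 to every gene alike and changes no place among random lists, so that the T and NK cell list at 0.17 and interferon response at 0.94 show nothing particular to them: every list between -0.54 and 0 changes sign. With members of at least 10 TPM the T and NK cell list was -1.29.

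Variable genes, co-expression and contrasts. Shared variable genes numbered 147 in the top twentieth (7.36 times the independent number), 64 in RPKM and 88 among genes in 24 cells of each mouse, where fewer genes were ranked; with detected-gene number removed the correlation of spreads was 0.587. Without the dendritic cell-like cells co-expression was 0.061 and 0.16 for the stem and early progenitor list and 0.062 and 0.17 for the dendritic list. Without removing detected-gene number it was, in mouse 1, 0.44 for the granulocyte-monocyte progenitor and 0.39 for the dendritic list. In RPKM it was 0.49 for granulocyte-monocyte progenitor, 0.30 for dendritic and 0.43 for G2 and M phase in mouse 1, and 0.35 for dendritic in mouse 2. The dendritic cell-like contrast of the interferon list in mouse 2, -0.55, reversed to 0.49 with k-means and with 5 components, 0.27 with mouse alone or neither removed, and 0.13 in RPKM. That of apoptosis and p53 in mouse 1, 0.57, reversed to -0.13 with mouse alone or neither removed and -0.14 in RPKM. The correlation of TPM and RPKM within a cell reversed to -0.21 over genes at 1 or more in both.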

Other observations

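Of the tests in this part, that on a panel of other genes was written before its result, and all others, as well as the division into 4 clusters, were chosen only after the result was seen. In the cells outside the dendritic cell-like group (34 in mouse 1, 27 in mouse 2, with mouse alone removed), scores of the stem and early progenitor list ran against those of the granulocyte-monocyte list. Over these cells the scores of both lists had a Spearman correlation of -0.47 in mouse 1 and -0.73 in mouse 2, and -0.45 and -0.71 over the 33 and 19 cells left without the neutrophil gene-led cluster described below. Members of the stem list had a mean correlation with each other of only 0.061 and 0.16 in the cells outside the dendritic cell-like group, lower than over all cells. Its score may therefore not stand for a program shared by its members. The stem and early progenitor list went with cytosolic ribosome genes (0.52 and 0.53) and with STAT5 and MAPK feedback targets (0.37 and 0.46). The granulocyte-monocyte list went with the monocyte list (0.60 and 0.34) and with glycolysis (0.35 and 0.43), G2 and M phase ran against ribosome genes (-0.32 and -0.59), ribosome genes went with STAT5 and MAPK feedback targets (0.36 and 0.44), and the dendritic list with myeloid transcription factors (0.30 and 0.47). These are the pairs with the same sign and a size of at least 0.3 in both mice out of 66 computed, chosen after their values were seen, with no p because cells are not replicates. Without the neutrophil gene-led cells, G2 and M phase against ribosome genes did not hold in mouse 2 (-0.26 and 0.00), the stem list with ribosome genes fell to 0.24 in mouse 2, and the other pairs kept their sign at 0.3 or more in both mice.

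At 4 clusters, the unnamed cells divided into 3 groups. A group led by Gpr56, Tmem176b, Ifitm1, Socs2, Muc13, Plac8, Ptprcap, Angpt1, Cd27 and Meis1, several of them genes of early progenitors, held 16 of 48 cells of mouse 1 (33.3%, 20.4 to 48.4) and 7 of mouse 2 (14.6%, 6.07 to 27.8). A group led by Tomm5, Fabp5, Cdk4 and Clpp held 21 cells of each mouse. A group led by Camp, Ngp, S100a9 and S100a8 held 8 cells of mouse 2, where mean S100a8 was 133623 TPM against 5720 in the other cells, and 1 cell of mouse 1. For that cell of mouse 1 the name does not hold, since it had S100a8 at 41.9 TPM, Camp at 6.13 and Lcn2 at 0. In the others of its mouse the means were 45.7, 13.1 and 11.8. Other leading genes were higher in it than in the others of its mouse, such as Cybb (173 against 9.88) and Ngp (20.1 against 13.1). That cell also had the fewest recovered reads of its mouse (148287 against a median of 362500). Of these 8 cells of mouse 2, 3 had more detected genes than the median of the others (interval 8.52 to 75.5%) and 1 had Kit at 10 TPM or more (0.316 to 52.7%). These values did not decide between explanations for the group, and none is offered.

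Transcripts of several late neutrophil genes, such as Ngp and S100a8, were found at a low level in most cells of both mice, whereas Retnlg, Mmp8, Mmp9, Cd177 and Il1b, named after their values were seen, had a median of 0. Expression by the cells of mouse 1 themselves is argued against in the case of Ngp by its median, which at positions of the numbering without a high cell was 0.0384 of that at positions with one. Free RNA within a capture round is argued against by the median ratio of mouse 2 to mouse 1 below 1000 TPM, which was 1.08 although mouse 2 held nearly all high cells. Carry-over of reads between libraries that share a position by 8 is a candidate explanation: after 11 genes had been looked at, a panel of 9 others had a median correlation of 0.52 between level and high cells at the position, against at most 0.13 for the other groupings and 0.135 for the highest of 100 reshufflings. Of the 9, 3 were late neutrophil genes and the other 6 were divided, with Ly6c2, Dnase1l3 and Fcnb at 0.48 to 0.54 and Cyb5, Hfe and Fis1 at 0.098 to 0.19 (named after their values were seen); Fcnb is also a leading gene of the neutrophil gene-led cluster, so it shares source cells with the late neutrophil genes. A further 94 less abundant genes, added after the panel was seen, had a median of 0.02, so the pattern was seen for some of the most abundant transcripts. Carry-over from high cells does not account for Cxcr2, which had medians below 1000 TPM of 24.1 and 30.4 TPM, the highest of the list, and no cell at 1000 TPM in either mouse; its level is left open. The labels do not give the layout of library indexes, so a shared index stays a hypothesis, and no biological explanation other than expression was tested.

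Dendritic cell-like cells made up 14 and 21 of 48 cells with mouse alone removed. Capture of 2 cells in 1 chamber is argued against as the source of the whole group, for a dendritic with another cell of typical gene number, since 0 of 14 and 0 of 21 had more detected genes than the median of the others (higher exact upper bound 23.2%; first written as a ratio of medians, 0.734 and 0.650, and restated as a share after the values were seen), but chambers with a pair of dendritic cells are not excluded. Of the 21 cells of mouse 2, 1 had S100a8 and Ngp at 1000 TPM or more. Its H2-Aa was only 114.54 TPM, so its place in the group is less certain, although Cd74 was at 1000 TPM or more in all 21. Another had Mpo at 1000 TPM or more, with H2-Aa at 6732 TPM. Since neutrophil gene-high cells had a median of 2821 genes, a shared chamber stays open for such cells. Both cells also had the fewest recovered reads of all (73986 and 96583, against a median of 333554 over both mice). Their mixed profiles therefore rest on the poorest libraries and are less certain. Carry-over is argued against by H2-Aa, whose median in the dendritic cell-like cells was 266 times the highest level outside them. This does not cover the cell with H2-Aa at 114.54 TPM. Cells without Kit transcript, left in the suspension, are argued against as the whole group, since Kit was at 10 TPM or more in 8 of 14 and 10 of 21 (lower bound at least 25.7%), and for the remaining cells this stays open. Whether these cells carry the leukemic genotype was not tested, nor was any biological explanation.

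RPKM values were far below TPM values for most genes. Lower expression of those genes is argued against, since the median log2 TPM of the genes before the split points minus that of the genes after them was -0.043. Read positions and gene coordinates from different genome builds are a candidate explanation: 50.3% of the genes with a high ratio were followed along the chromosome by another such gene, chromosome 16 left out, against at most 15.4% in 100 reshufflings of the gene order. An earlier measure, the share of genes that 1 split per chromosome placed right, gained little (95.9% against at most 93.1%), and the number of exons had a Spearman correlation of 0.09 with the ratio after the split. Presence among the RPKM genes, as opposed to the ratio, rose with exon number. Of genes with a mean of 10 TPM, it was 22.5% with 1 exon, 51.2% with 2 exons and 87.2% with 3 or more. No mm9 annotation was used here, so the hypothesis was not tested directly.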
